A study of Mus musculus with 32 samples.

How the data were processed

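Kidney RNA of 32 male mice was hybridised to 1-colour Agilent 4x44k version 2 mouse arrays, 1 animal per array. The labels put the arrays in 8 groups of 4, made of 2 genotypes, wild type C57BL/6 and miR-155-/-, and 4 times after 1 injection, 0, 24, 48 and 72 h. The 0 h group received saline and the others cisplatin. Per the labels' extract protocol each array held RNA of a different animal, so the 4 arrays of a group were treated as independent animals.

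Per the file headers, the arrays were read with Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09, which subtracted the background and removed spatial trends from each array. The intensity used here was the deposited processed signal, 1 linear value per spot, per the file headers. The authors' deposited value table holds a linear intensity as well. Set against the scanner values it was the processed signal times 1 factor per array, which put the 75th percentile of every array at 999.3 to 1000. Its scale was thus found to be linear, and it was not centred by gene. The software that made it is not given in the sources used here.

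Each array held 43020 spots that were not controls, of 39429 probes. The files carried no gene symbol, so symbols were taken through the transcript accession of each probe from a RefSeq gene table of the assembly GRCm38.p6. This gave 1 symbol for 27234 probes (69.1%) and none for 12195, for 20659 named genes. The arrays were annotated on another assembly, so that the table was used for names and for which genes neighbour each other and no coordinate is given.

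The processed signal was taken to log2, and the 75th percentile of each array over its non-control spots was subtracted. That percentile lay between 1531 and 2647 in intensity units. Spots carrying an outlier flag, 59 to 976 per array, were left out on that array, and 0 spots were saturated. Spots of a probe were averaged on the log2 scale, and of several probes of a gene the brightest over all 32 arrays stood for it. A gene was tested if its probe was well above background on all 4 arrays of at least 1 group and at least 3 of 4 values were left in every group. This left 23749 genes and transcripts, 16461 of them with a symbol (79.7% of those named on the array), with 971 missing values. Between 68.8% and 82.2% of the probes of an array were well above background.

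Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend), as 8 group means fitted over all 32 arrays with 24 residual degrees of freedom and a median of 3.8 prior ones. All tests were 2-sided. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 13 comparisons were cisplatin against saline at 3 times in each genotype, miR-155-/- against wild type at 4 times, and the difference between the genotypes' responses (the interaction) at 3 times. A ± after a log2 difference is its standard error from the fit, with 4 arrays in each group. A probe that was not well above background on any of the 4 arrays of a group gave a bound, written "at least N-fold". It sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's own value and the lowest value among probes well above background.

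The genes named are Havcr1, Lcn2, Clu, Spp1, Cdkn1a, Mdm2, Gdf15, Fos, Atf3 and Hmox1 in every comparison. Added to them, per comparison, are the 6 named genes with the largest rise and the 6 with the largest fall among called genes whose 4 and 4 values did not overlap, which chance gives for 2.86% of genes. Up to 4 called members of each list with the smallest adjusted p serve as examples, and in each interaction the 10 called genes with the smallest adjusted p. This rule, the gene lists, the tests and the alternatives were fixed before the data were examined. The genotype genes called at several times, and single genes that are said to have been picked afterwards, are exceptions. The values of 1 gene that the rule selects are not reported here.

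The 27 gene lists were tubular injury markers; p53 target genes; immediate early and AP-1 genes; inflammatory cytokines, chemokines and adhesion molecules; interferon-stimulated genes; cell death genes; S phase and mitosis genes; Nrf2 and glutathione genes; the unfolded protein and integrated stress response; cisplatin transport and metal handling; proximal tubule; distal nephron and collecting duct; fatty acid oxidation and PPAR alpha genes; oxidative phosphorylation; cholesterol synthesis; circadian clock. Further lists held markers of fibroblasts and matrix, macrophages and monocytes, neutrophils, lymphocytes, endothelium, podocytes, red blood cells, adipocytes and adrenal cortex, published miR-155 target genes, and genes reported to differ between C57BL/6J and C57BL/6N. Each list with at least 4 tested members, 26 of them, was tested against the other genes with camera at a preset correlation of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a set moves one way on balance and compares it with no other genes, were run beside it. Most list calls were lost with an estimated correlation. For members of a list the number called over all genes is given. The number adjusted over the list alone follows where it differs. A list's shift is the median log2 difference of its tested members.

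The arrays lay on 8 slides of 4, read on 2 scan days, and each slide held 4 arrays of different groups. Every comparison was therefore also fitted with slide as a fixed block. Each was also computed within slides that held both groups, on the arrays of the calls. The other alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited value table, no filter on dim probes, flagged spots kept, the mean of all probes of a gene, no variance trend, array weights, only the groups compared, a replicate block, a 2-fold threshold and leaving out each array in turn. The files carry no mean signal, so normexp was run on the median signal and median background. Scan day as a block, and both divergent miR-155-/- arrays left out, were added after the data were seen. The test of genes with miR-155 seed sites was not run, since it needs 3-prime UTR sequences, which were not used here.

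The fit was tested on simulated data with 100 genes changed by each size among 22833 genes. For miR-155-/- against wild type at 72 h it recovered 71% of 2-fold and 91% of 4-fold changes, and for the interaction at 72 h it recovered 58% and 84%. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.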

Results

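Whole kidneys of male mice aged 12 to 16 weeks were profiled after 1 injection of 20 mg/kg cisplatin, a platinum drug that damages DNA and is toxic to the tubule cells that take it up. The mice were wild type C57BL/6 or lacked miR-155, a microRNA of immune and stressed cells. Kidneys were taken at 24, 48 and 72 h, and saline-injected mice of each genotype served as the 0 h groups. Each of the 8 groups held 4 animals, 1 array per animal.

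The first component of variation over all genes (40.4% of the variance) set the saline arrays apart from the treated ones, and the second (15.8%) followed the time after the drug. All 8 saline arrays lay between -93.17 and -75.06 on the first component, and the treated arrays between -13.66 and 121. miR-155-/- replicate 3 at 48 h (121 and 61.5 on the first and second components) stood apart from its group, and miR-155-/- replicate 3 at 24 h (87.7 and 59.7) stood at the edge of its own.

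**Figure D1:**
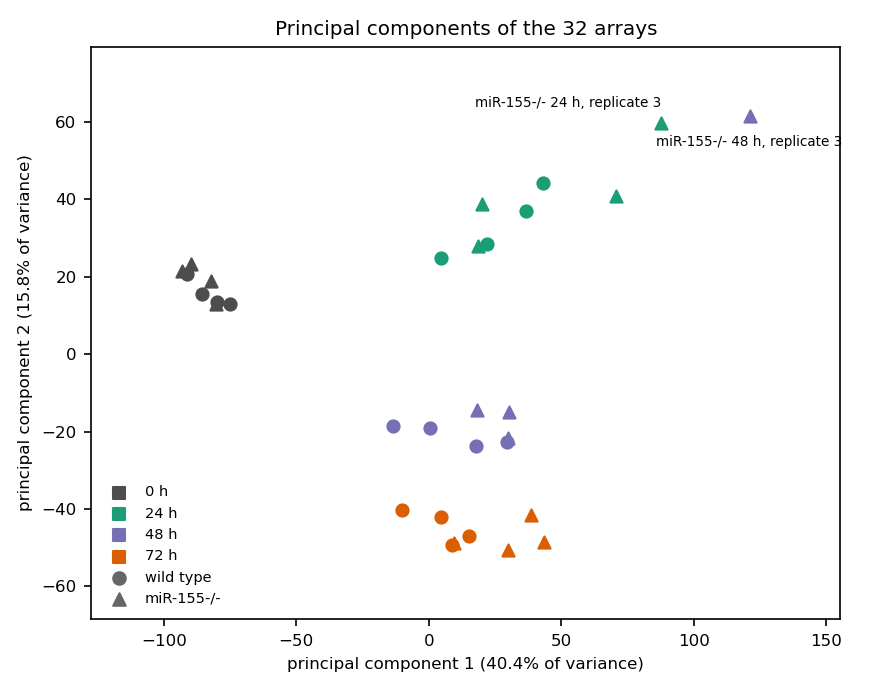
Scores of the 32 arrays on the first and second principal components of the log2 values (arbitrary units), 1 point per array, coloured by time and shaped by genotype. The saline arrays sit at the left, from -93.17 to -75.06 on the first axis, and miR-155-/- replicate 3 of 48 h sits at the upper right (121, 61.5).

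At 24 h in wild type kidney, p53 target genes, immediate early genes and markers of tubular injury rose and tubular transport genes fell, against saline (4 arrays per group). All 29 measured p53 target genes rose, with a median log2 difference of 2.03. Cdkn1a, an inhibitor of the cell cycle, rose 33.5-fold (log2 5.07 ± 0.29) and Phlda3, which restrains Akt, 18.7-fold (4.23 ± 0.16). Mdm2, which marks p53 for degradation, rose 4.09-fold and Gdf15, a stress hormone, 13.9-fold (3.80 ± 0.21). The list's adjusted p was 3.47e-28, and 0.000867 with an estimated correlation.

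Of the 19 tubular injury markers 9 rose (median 0.94). Havcr1, the tubular injury protein Kim-1, rose 22.0-fold (4.46 ± 0.64) and Krt20, a keratin, 46.8-fold (5.55 ± 0.66). Lcn2, the injury marker NGAL, stood 1.91-fold higher and was not called (0.94 ± 0.68, adjusted p = 0.290), and Clu and Spp1 did not pass the test either. Of 17 immediate early and AP-1 genes 15 rose (median 2.11), among them Fosl1 49.8-fold, Atf3 12.5-fold and Fos 12.5-fold. Of 23 inflammatory genes 11 rose and 1 fell (median 0.64), led by the neutrophil attractant Cxcl1 at 16.9-fold (4.08 ± 0.36) and the TWEAK receptor Tnfrsf12a at 12.8-fold (3.68 ± 0.28). These 3 lists had adjusted p of 0.0154, 9.86e-07 and 0.00256, and adjusted p = 0.563, 0.35 and 0.556 with an estimated correlation. Of 16 Nrf2 and glutathione genes 12 rose and 1 fell (median 1.19), with the glutathione transferase Gsta2 at 4.12-fold and haem oxygenase Hmox1 at 5.86-fold. Of 21 cell death genes 10 rose (11 adjusted over the list alone) and 1 fell (median 0.35), with Bcl2l11, which promotes apoptosis, at 6.12-fold. Adjusted p was 9.86e-07 and 0.0109 for these 2 lists, and adjusted p = 0.0861 and 0.379 with an estimated correlation.

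Of 24 proximal tubule genes 22 fell and 0 rose (median -1.0), among them the endocytic receptors Lrp2 (fell by 2.24 ± 0.22 on the log2 scale) and Cubn (fell by 2.08 ± 0.25) and the phosphate transporter Slc34a1 (fell by 1.51). Of 22 distal nephron and collecting duct genes 15 fell (median -1.24), with the growth factor Egf (fell by 3.07 ± 0.28) and the thiazide-sensitive transporter Slc12a3 (fell by 2.47). Of 15 cholesterol synthesis genes 8 fell and 1 rose (median -0.73), with Idi1 (fell by 1.75 ± 0.22). Of 15 oxidative phosphorylation genes 12 fell (14 adjusted over the list alone), each by little (median -0.33). Adjusted p was 2.09e-09, 9.86e-07, 0.00196 and 1.01e-05 for these 4 lists, and adjusted p = 0.157, 0.178, 0.157 and 0.350 with an estimated correlation. The macrophage list moved with them: 5 of 15 markers fell (10 adjusted over the list alone) and 1 rose, with a median of -0.70. So did the fibroblast and matrix list, of which 7 of 15 fell (8 adjusted over the list alone) and 1 rose, with a median of -0.68. Adjusted p was 0.0120 and 0.0250, and adjusted p = 0.556 and 0.645 with an estimated correlation.

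The other lists were not called at 24 h. Of 15 interferon-stimulated genes 5 rose (median 0.35, adjusted p = 0.175). Of 22 S phase and mitosis genes 4 rose and 6 fell (median -0.28, adjusted p = 0.218). The mitotic gene Mki67 fell (by 1.70 ± 0.32), while the replication clamp Pcna rose 1.86-fold (0.89 ± 0.20). Of 13 genes of the unfolded protein and integrated stress response 4 rose and 6 fell, with a median of -0.32 against a mean of 0.10 (adjusted p = 0.458). Markers of neutrophils (0 of 9), lymphocytes (1 of 12 fell, 0 adjusted over the list alone), endothelium (2 of 11 fell, 1 adjusted over the list alone), podocytes (1 of 9 fell, 0 adjusted over the list alone), red blood cells (1 of 7 rose), adipocytes (1 of 6 rose) and adrenal cortex (0 of 3, too few for a set test) were called in few cases. The red blood cell score stood 1.48 lower and the lymphocyte score 0.35 lower on the log2 scale, each on 4 of 4 arrays.

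By size, the named genes that rose most were Tac1, a neuropeptide precursor, at 79.2-fold (6.31 ± 0.75; well above background on 1 of 4 saline arrays), Serpina7 at 61.8-fold (5.95 ± 0.47; 2 of 4), Fosl1, Krt20, Zfp365 at 33.6-fold (5.07 ± 0.23) and Cdkn1a. Those that fell most were Erc2 (fell by 6.61 ± 0.40) and the major urinary protein genes Mup18 (fell by 7.03 ± 1.29), Mup17 (fell by 6.92 ± 1.12), Mup19, Mup20 and Mup3 (at least 16.7-fold); Mup17 and Mup20 were well above background on 1 of 4 treated arrays. The Mup genes are near-identical copies whose probes cannot be told apart with certainty, so that no single one of them is certain, and the same holds for the Speer, Lce, Sprr2, Rbmy and globin genes.

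With limma 9182 of 23749 genes were called, 4996 higher and 4186 lower, of which 3228 changed at least 2-fold. All 99 called named genes had every treated array beyond the saline mean (4 arrays, and 3 for Atf3), as the rule requires of the largest rises and falls. With slide as a block 5994 were higher and 5210 lower, and within slide 6, the one slide with both groups, 99.8% of the called genes kept their sign. The shifts with slide as a block and within slide 6 were 1.94 and 2.14 for p53 targets, 1.43 and 1.38 for injury markers, 2.25 and 2.79 for AP-1 genes, 0.59 and 1.18 for inflammatory genes, 1.33 and 1.26 for Nrf2 genes, -1.10 and -1.13 for the proximal tubule, -1.42 and -1.56 for the distal nephron and -0.70 and -0.81 for cholesterol synthesis. Of the 27 lists 22 kept their sign there. Under normexp 5247 genes were called.

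**Figure D2:**
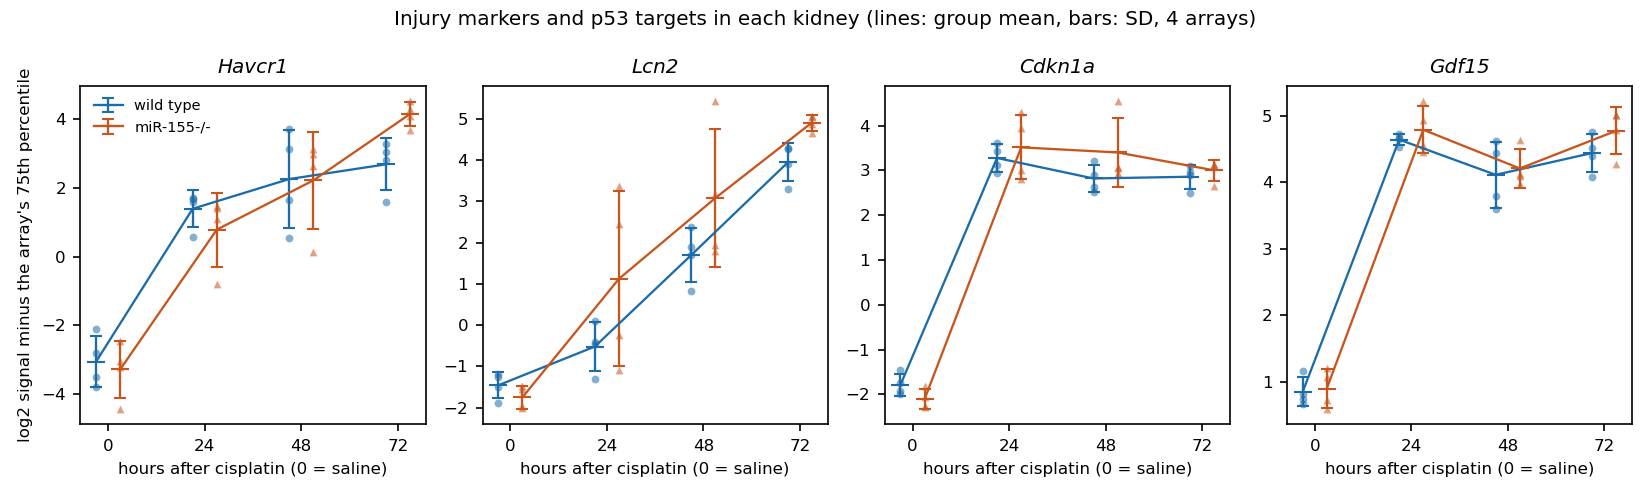
Values of Havcr1, Lcn2, Cdkn1a and Gdf15 (log2 signal relative to the array's 75th percentile) against hours after the injection, 1 point per array, with the mean and SD of each group of 4 and 0 h standing for saline. Cdkn1a and Gdf15 are raised from 24 h on, and Havcr1 and Lcn2 are highest at 72 h in miR-155-/- kidneys, 174-fold and 101-fold above saline.

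At 48 h in wild type kidney the p53 response stood at a similar height, injury and inflammatory genes rose in larger numbers, and globin transcripts fell. Of 29 p53 targets 27 rose (median 1.94; adjusted p = 2.45e-38, and 0.000102 with an estimated correlation), with Cdkn1a at 24.4-fold (4.61 ± 0.29), Gdf15 at 9.65-fold and Mdm2 at 3.75-fold. Of the 19 injury markers 12 rose (13 adjusted over the list alone; median 1.48), with Havcr1 at 40.1-fold (5.32 ± 0.64), Krt20 at 52.1-fold, the fibrinogen chain Fgg at 16.1-fold (4.01 ± 0.61), Lcn2 at 8.92-fold (3.16 ± 0.68) and the matrix phosphoprotein Spp1 at 2.78-fold (1.48 ± 0.23). Of 23 inflammatory genes 15 rose (median 1.65), with Cxcl1 at 18.7-fold and the acute phase gene Saa3 at 11.4-fold (3.51 ± 0.37). Of 17 AP-1 genes 14 rose (median 1.70), with Fos at 12.1-fold and Atf3 at 15.7-fold. Adjusted p was 1.74e-08, 3.65e-09 and 3.15e-09 for these 3 lists, and adjusted p = 0.103, 0.103 and 0.147 with an estimated correlation.

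Of 15 interferon-stimulated genes 8 rose (9 adjusted over the list alone; median 0.88). Cell death genes rose in 10 of 21 cases and fell in 1 (3 adjusted over the list alone; median 0.36). Adjusted p was 9.46e-05 and 0.00317 for these 2 lists, and adjusted p = 0.244 for each with an estimated correlation. Of 16 Nrf2 genes 12 rose and 1 fell (median 0.85; adjusted p = 2.50e-08, and 0.0336 with an estimated correlation), with Hmox1 at 2.76-fold. Of 15 cholesterol synthesis genes 7 fell (median -0.43; adjusted p = 1.35e-05, and 0.0336 with an estimated correlation).

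Proximal tubule genes fell in 12 of 24 cases (13 adjusted over the list alone; median -0.76), with the amino acid transporter Slc7a13 (fell by 2.85 ± 0.34). Distal genes fell in 9 of 22 (median -0.62). Oxidative phosphorylation genes fell in 7 of 15 (8 adjusted over the list alone; median -0.27), and S phase and mitosis genes fell in 9 of 22 (10 adjusted over the list alone) and rose in 1 (median -0.43). Adjusted p was 4.37e-09, 5.68e-07, 9.90e-05 and 0.00210 for these 4 lists, and adjusted p = 0.120, 0.126, 0.296 and 0.448 with an estimated correlation. Markers of blood and of macrophages moved with them. Of 7 red blood cell markers 6 fell (median -4.22), and 6 of 15 macrophage markers fell (median -0.66). Adjusted p was 0.00169 and 0.00150, and adjusted p = 0.311 and 0.301 with an estimated correlation.

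The largest rises were those of Tac1 (6.58 ± 0.75), Lce1d (6.28 ± 0.84), Ifi27l2b, an interferon-inducible gene, at 65.6-fold (6.04 ± 0.38; well above background on 2 of 4 saline arrays), Serpina7, Lce1g and Zfp365 (5.86 ± 0.23). The largest falls were those of Immp2l (at least 51.8-fold), Hbb-bt (fell by 5.52 ± 1.26), Hbb-bs (1 of 4 treated arrays), Mup17, Mup18 and Mup19. With limma 5655 genes were called, 2906 higher and 2749 lower (1971 at least 2-fold). All 97 called named genes had 4 of 4 treated arrays beyond the saline mean. Under the slide block 3789 were higher and 4411 lower, and within slides 2 and 4 the sign was kept by 99.3% and 99.96% of them. Fitted with slide as a block, within slide 2 and within slide 4 the shifts were 1.92, 1.70 and 1.99 for p53 targets, 1.54, 0.79 and 1.99 for injury markers, 1.27, 0.94 and 2.07 for inflammatory genes, 0.70, 0.50 and 0.55 for interferon genes and 1.07, 0.70 and 1.17 for Nrf2 genes. They were -0.97, -0.28 and -1.40 for the proximal tubule, -0.78, -0.58 and -0.56 for the distal nephron, -0.44, -0.28 and -0.32 for cholesterol synthesis, -0.44, -1.22 and -0.54 for S phase genes and -3.82, -3.99 and -5.89 for red blood cell markers. Under normexp 2978 genes were called, and 11018 with array weights.

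At 72 h in wild type kidney the injury marker Havcr1 stood 53.9-fold (5.75 ± 0.64) and Lcn2 42.2-fold (5.40 ± 0.68) above saline, and replication genes fell. Of the 19 injury markers 13 rose (median 1.88), with Spp1 at 4.82-fold (2.27 ± 0.23) and the chaperone Clu at 1.99-fold (0.99 ± 0.21). Of 17 AP-1 genes 13 rose (14 adjusted over the list alone; median 1.65), with Fos at 14.5-fold and Atf3 at 12.0-fold, and of 23 inflammatory genes 13 rose (14 adjusted over the list alone) and 3 fell (median 1.45). Adjusted p was 5.64e-09, 1.32e-08 and 3.40e-06 for these 3 lists, and adjusted p = 0.0914, 0.224 and 0.224 with an estimated correlation. Of 29 p53 targets 27 rose (median 1.97; adjusted p = 1.08e-34, and 0.00021 with an estimated correlation), with Cdkn1a at 25.1-fold, Gdf15 at 12.1-fold and Mdm2 at 3.73-fold.

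Of 22 S phase and mitosis genes 12 fell and 0 rose (median -0.78), with the replicative helicase subunit Mcm6 (fell by 0.83 ± 0.11). Proximal genes fell in 11 of 24 cases (12 adjusted over the list alone) and rose in 1 (median -0.39), and distal genes fell in 7 of 22 (median -0.43). Adjusted p was 7.30e-05, 9.12e-06 and 2.63e-04 for these 3 lists, and adjusted p = 0.352, 0.250 and 0.288 with an estimated correlation. Of 19 fatty acid oxidation genes 10 rose and 1 fell (median 0.46), with the thioesterase Acot2 at 2.74-fold. Interferon genes rose in 7 of 15 cases (8, with 1 fallen, adjusted over the list alone; median 0.72) and cell death genes in 9 of 21 with 3 fallen (4 adjusted over the list alone; median 0.38). Oxidative phosphorylation genes fell in 3 of 15 (median -0.13). Adjusted p was 0.00233, 0.00825, 0.0164 and 0.0137 for these 4 lists, and adjusted p = 0.352, 0.352, 0.352 and 0.411 with an estimated correlation. Of 16 Nrf2 genes 12 rose and 1 fell (median 0.88; adjusted p = 3.12e-08, and 0.0236 with an estimated correlation), and of 15 cholesterol genes 8 fell (11 adjusted over the list alone; median -0.51; adjusted p = 1.83e-07, and 0.0105 with an estimated correlation).

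Markers of other cells fell beside these groups. Of 15 macrophage markers 11 fell (14, with 1 risen, adjusted over the list alone; median -0.99), of 15 fibroblast and matrix genes 8 fell (9 adjusted over the list alone) and 1 rose (median -0.95), and of 12 lymphocyte markers 4 fell (5 adjusted over the list alone; median -0.52). Of 7 red blood cell markers 6 fell (median -5.62). Adjusted p was 1.39e-05, 0.00205, 0.0316 and 2.60e-05 for these 4 lists, and adjusted p = 0.224, 0.352, 0.352 and 0.235 with an estimated correlation. A further probe of the macrophage gene Itgam stood at 0.15 where the one used gave -1.65.

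Il1f6, an epithelial cytokine, rose most among named genes (97.4-fold, 6.61 ± 0.63), before Havcr1, Zfp365 (5.67), Tac1 (5.55), Rbmy (5.52) and Sprr2e (at least 15.9-fold). Hbb-bt (fell by 7.34; well above background on 2 of 4 treated arrays, as Mup18 and Mup17), Immp2l (at least 57.6-fold), Hbb-bs (at least 24.4-fold), Mup18, Mup17 and Mup19 fell most. With limma 6018 genes were called, 2973 higher and 3045 lower (2321 at least 2-fold). All 105 called named genes had 4 of 4 treated arrays beyond the saline mean. No slide held both groups, so no within-slide value exists. Once slide entered as a block, 3453 were higher and 3944 lower, and the shifts were 1.85 for injury markers, 1.95 for p53 targets, -0.71 for S phase genes, -0.56 for the proximal tubule, 0.45 for fatty acid oxidation, -1.33 for macrophages and -5.43 for red blood cells, while the interferon (0.43, adjusted p = 0.0506) and oxidative phosphorylation (-0.11, adjusted p = 0.108) lists were no longer called. Under normexp 3044 genes were called, with array weights 12564, and with the compared groups alone 9734.

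**Figure D3:**
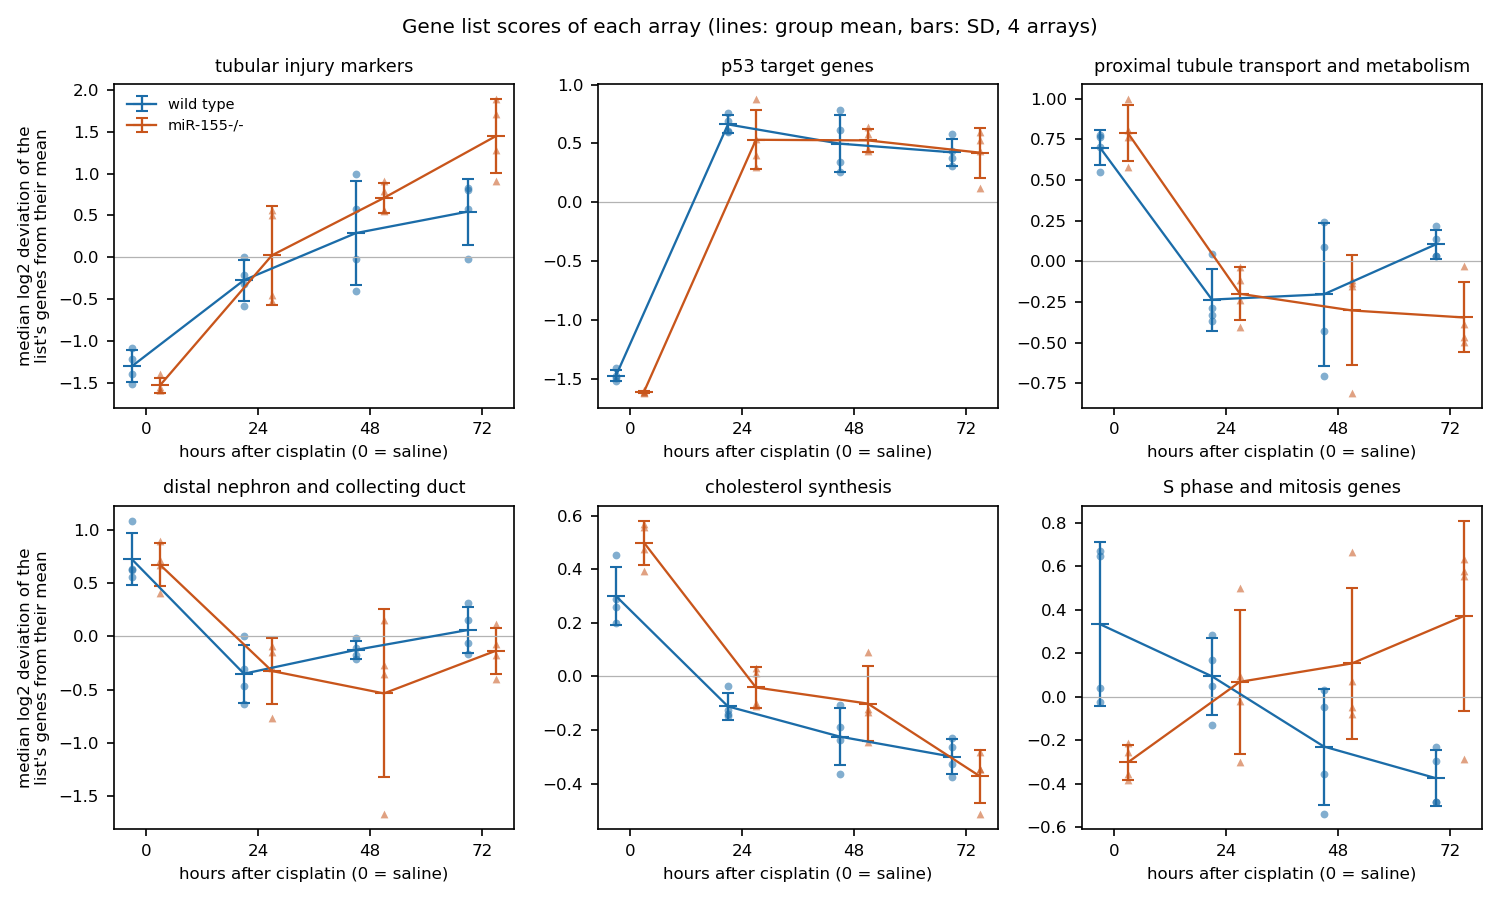
Scores of 6 gene lists (median log2 deviation of the members from their mean over all arrays) against hours after the injection, 1 point per array, with the mean and SD of each group of 4. The p53 targets are raised at all 3 treated times in both genotypes, and the S phase score is 0.74 higher in miR-155-/- than in wild type kidneys at 72 h.

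In miR-155-/- kidney at 24 h all p53 targets but 1 rose (28 of 29, median 1.95; adjusted p = 3.31e-24, and 0.00226 with an estimated correlation), with Cdkn1a at 49.3-fold (5.62 ± 0.29), Gdf15 at 14.9-fold and Mdm2 at 4.38-fold. Injury markers rose in 13 of 19 cases (median 1.55), with Krt20 at 75.8-fold (6.24 ± 0.66), Havcr1 at 16.9-fold (4.08 ± 0.64) and Lcn2 at 7.31-fold (2.87 ± 0.68). AP-1 genes rose in 15 of 17 (median 2.28), with Fosl1 at 104-fold, Atf3 at 18.3-fold and Fos at 17.8-fold, and inflammatory genes in 13 of 23 (median 1.01). Adjusted p was 3.29e-04, 4.56e-07 and 1.21e-04 for these 3 lists, and adjusted p = 0.316, 0.305 and 0.316 with an estimated correlation. Nrf2 genes rose in 11 of 16 cases with 1 fallen (median 1.49), and cell death genes in 13 of 21 (13, with 1 fallen, adjusted over the list alone; median 0.59). Adjusted p was 4.47e-06 and 0.00105, and adjusted p = 0.122 and 0.236 with an estimated correlation.

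Proximal tubule genes fell in 22 of 24 cases (23 adjusted over the list alone; median -1.03), and distal genes in 14 of 22 (median -0.86). Cholesterol synthesis genes fell in 8 of 15 (median -0.55) and oxidative phosphorylation genes in 8 of 15 (median -0.25). Adjusted p was 4.48e-07, 4.47e-06, 0.00501 and 0.00501 for these 4 lists, and adjusted p = 0.236, 0.236, 0.236 and 0.613 with an estimated correlation. S phase genes rose in 8 of 22 cases and fell in 3 (median 0.15, adjusted p = 0.296). Endothelial markers fell in 6 of 11 (median -0.58), fibroblast genes in 7 of 15 with 1 risen (median -0.68) and macrophage markers in 6 of 15 with 1 risen (median -0.76). Adjusted p was 0.0278, 0.0355 and 0.0273, and adjusted p = 0.613, 0.688 and 0.613 with an estimated correlation.

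Tac1 (106-fold, 6.73 ± 0.75), Fosl1, the keratins Krt12 (79.6-fold), Krt20 and Krt76 (at least 22.8-fold), and Serpina7 (at least 30-fold) rose most. In saline miR-155-/- kidneys, the reference at each time, Tac1, Krt12, Saa3 and Lce1g were well above background on 1 of 4 arrays. Mup18 (fell by 8.52; 2 of 4 treated arrays), Mup17 (fell by 8.26; 1 of 4), Mup3 (at least 68.5-fold), Mup19, Mup20 and Serpina3k (at least 35.4-fold) fell most. With limma 11667 genes were called, 6325 higher and 5342 lower (4443 at least 2-fold). All 105 called named genes had 4 of 4 treated arrays beyond the saline mean. Without both divergent arrays 6654 were higher and 5785 lower, with 13 injury markers, 28 p53 targets and 15 AP-1 genes risen and 23 proximal genes fallen, while the macrophage, fibroblast and endothelial lists (-0.57, -0.96 and -0.55) were no longer called (adjusted p = 0.0658, 0.0574 and 0.0735). With slide as a block the counts were 7275 and 6471, and within slides 4 (where replicate 3 is the treated array) and 6 the sign was kept by 97.6% and 99.9% of the called genes. Under the slide block, within slide 4 and within slide 6 the shifts were 2.01, 2.31 and 2.26 for p53 targets, 1.43, 1.64 and 1.99 for injury markers, 2.51, 3.90 and 2.52 for AP-1 genes and 0.98, 1.38 and 1.41 for inflammatory genes. They were -1.02, -0.88 and -1.27 for the proximal tubule, -0.96, -1.30 and -1.13 for the distal nephron, and -0.78, -0.32 and -1.14 for fibroblasts and -0.54, -0.93 and -0.74 for endothelium, the last 2 lists no longer called with the block (adjusted p = 0.0831 and 0.0687). Under normexp 7144 genes were called.

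In miR-155-/- kidney at 48 h injury and inflammatory genes rose further in number. Injury markers rose in 17 of 19 cases (median 1.93), with Havcr1 at 45.6-fold (5.51 ± 0.64), Lcn2 at 28.4-fold (4.83 ± 0.68), Spp1 at 3.80-fold and Clu at 1.64-fold. Inflammatory genes rose in 19 of 23 (median 1.97), and AP-1 genes in 15 of 17 (median 2.21), with Atf3 at 31.4-fold and Fos at 19.7-fold. Adjusted p was 7.33e-09, 7.92e-11 and 7.33e-09, and adjusted p = 0.105, 0.105 and 0.158 with an estimated correlation. Of 29 p53 targets 28 rose (median 1.96; adjusted p = 4.15e-28, and 0.000882 with an estimated correlation), with Cdkn1a at 45.6-fold (5.51 ± 0.29), Gdf15 at 9.95-fold and Mdm2 at 3.78-fold. Interferon genes rose in 10 of 15 cases (10, with 1 fallen, adjusted over the list alone; median 0.80), Nrf2 genes in 10 of 16 with 1 fallen (median 1.30) and cell death genes in 13 of 21 (14 adjusted over the list alone; median 0.58). Adjusted p was 7.41e-04, 7.70e-05 and 1.70e-04, and adjusted p = 0.354, 0.105 and 0.105 with an estimated correlation.

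Proximal genes fell in 20 of 24 cases (median -1.16), and distal genes in 16 of 22 (median -1.16). Cholesterol genes fell in 7 of 15 (median -0.32) and oxidative phosphorylation genes in 9 of 15 (median -0.29). Adjusted p was 7.33e-09, 5.09e-07, 0.00174 and 3.33e-04, and adjusted p = 0.105, 0.105, 0.105 and 0.354 with an estimated correlation. Fatty acid oxidation genes fell in 6 of 19 cases and rose in 2 (median -0.30), and macrophage markers fell in 6 of 15 and rose in 1 (median -0.69). Adjusted p was 0.0437 and 0.0242, and adjusted p = 0.593 and 0.590 with an estimated correlation. S phase genes rose in 10 of 22 cases with 1 fallen (median 0.18, adjusted p = 0.0779). Lymphocyte markers fell in 6 of 12 (median -0.50, adjusted p = 0.0779). Of these, Cd3d, Cd8a and Cd3g (-1.41, -1.33 and -1.74) turned to 0.16, 0.41 and 0.30 under normexp. Of 3 adrenal cortex markers 2 rose, Cyp21a1 and Hsd3b1 (at least 1.35-fold).

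The late cornified envelope genes Lce1d (275-fold), Lce1g, Lce1i (at least 108-fold) and Lce1f (at least 40-fold), with Tac1 (183-fold; 1 of 4 saline arrays) and Sprr2e (at least 40.7-fold), rose most. Mup18 (fell by 9.15; 2 of 4 treated arrays), Mup17 (1 of 4), Mup3 (at least 94.1-fold), Mup20, Mup19 and Serpina3k (at least 48.6-fold) fell most. With limma 10398 genes were called, 5386 higher and 5012 lower (3781 at least 2-fold). Of the 110 called named genes 109 had 4 of 4 treated arrays beyond the saline mean. Without both divergent arrays 4841 were higher and 4330 lower, 16 injury markers rose, 18 proximal genes fell and 2 of 12 lymphocyte markers fell, and the red blood cell list was called (6 of 7 fell; -2.78 in place of -1.20, adjusted p = 0.0384), while the proximal shift went to -0.75 and the interferon one to 1.20. The fatty acid oxidation (-0.15, adjusted p = 0.0834) and macrophage (-0.39, adjusted p = 0.135) lists were then no longer called. Fitted with slide as a block, the counts were 6897 and 6491, and within slide 1, the one slide with both groups, where the divergent replicate 3 is the treated array, 98.3% of the called genes kept their sign. With the slide block and within slide 1 the shifts were 2.06 and 2.15 for p53 targets, 2.17 and 2.46 for injury markers, 2.22 and 1.93 for inflammatory genes, 0.91 and 0.08 for interferon genes, -1.53 and -1.76 for the proximal tubule, -1.22 and -2.47 for the distal nephron and -0.33 and 2.63 for red blood cells. Under normexp 5187 genes were called, and 5808 with the compared groups alone.

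In miR-155-/- kidney at 72 h all 19 injury markers rose (median 2.89; adjusted p = 2.92e-16, and 0.0125 with an estimated correlation), with Havcr1 at 174-fold (7.45 ± 0.64), Lcn2 at 101-fold (6.66 ± 0.68), Spp1 at 7.39-fold (2.88 ± 0.23) and Clu at 3.29-fold (1.72 ± 0.21). Of 23 inflammatory genes 19 rose (median 3.20; adjusted p = 1.03e-12, and 0.0440 with an estimated correlation), with Saa3 at 47.3-fold (5.56 ± 0.37) and Cxcl1 at 33.7-fold. Of 29 p53 targets 28 rose (28, with 1 fallen, adjusted over the list alone; median 2.02; adjusted p = 2.53e-29, and 0.000668 with an estimated correlation), with Cdkn1a at 34.6-fold, Gdf15 at 14.7-fold and Mdm2 at 4.06-fold. Of 15 cholesterol genes 11 fell (13 adjusted over the list alone; median -0.77; adjusted p = 1.85e-07, and 0.0112 with an estimated correlation).

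AP-1 genes rose in 15 of 17 cases (median 1.97), with Atf3 at 17.1-fold and Fos at 15.8-fold, interferon genes in 10 of 15 (11 adjusted over the list alone; median 1.05), cell death genes in 12 of 21 with 2 fallen (13 and 2 adjusted over the list alone; median 0.67) and Nrf2 genes in 11 of 16 with 1 fallen (12 and 1 adjusted over the list alone; median 0.97). Adjusted p was 8.37e-09, 3.80e-04, 8.85e-05 and 1.71e-05, and adjusted p = 0.181, 0.297, 0.106 and 0.0819 with an estimated correlation. S phase genes rose in 10 of 22 (11 adjusted over the list alone; median 0.65), with the nucleotide reductase Rrm2 at 3.38-fold and the cyclin Ccne1 at 2.62-fold. Proximal genes fell in 18 of 24 (19 adjusted over the list alone; median -0.96), distal genes in 10 of 22 (median -0.62), and oxidative phosphorylation genes in 11 of 15 (12 adjusted over the list alone; median -0.41). Adjusted p was 0.00198, 1.51e-09, 7.49e-05 and 1.12e-05, and adjusted p = 0.5, 0.105, 0.219 and 0.219 with an estimated correlation. Fibroblast and matrix genes rose in 4 of 15 and fell in 1, and their median of -0.13 opposed the mean of 0.30 and the test (adjusted p = 0.536). Of 9 neutrophil markers 3 rose (median 0.10, adjusted p = 0.0898), the alarmins S100a8 at 10.9-fold and S100a9 by 3.42 on the log2 scale, and Retnlg at 18.4-fold (2 of 4 saline arrays well above background). Lymphocyte markers fell in 5 of 12 (6 adjusted over the list alone; median -0.86) and red blood cell markers in 6 of 7 (median -4.26). Adjusted p was 0.0419 and 0.00865, and adjusted p = 0.443 for each with an estimated correlation.

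Crct1 (218-fold, 7.77 ± 0.77), a gene of cornified epithelium, Rbmy, Il1f6 (196-fold; well above background on 2 of 4 saline arrays), Sprr2e (at least 49.1-fold), Havcr1 and the secreted neuroprotein Vgf (168-fold; 1 of 4) rose most, and Mup18 (fell by 8.69; 2 of 4 treated arrays), Mup17 (2 of 4), Mup19, Mup3, Mup20 and Mup4 (fell by 6.79) fell most. With limma 8367 genes were called, 4200 higher and 4167 lower (3316 at least 2-fold). Of the 111 called named genes 110 had 4 of 4 treated arrays beyond the saline mean. With slide as a block the counts were 5323 and 5527, and within slides 1 and 3 the sign was kept by 99.6% and 99.7% of the called genes. Under the slide block, within slide 1 and within slide 3 the shifts were 2.98, 2.80 and 2.82 for injury markers, 3.41, 2.87 and 2.57 for inflammatory genes, 2.04, 1.72 and 2.20 for p53 targets, 0.64, -0.01 and 0.99 for S phase genes, -1.19, -0.75 and -0.99 for the proximal tubule, and -0.64, -0.65 and -0.62 for cholesterol synthesis. They were -3.78, -6.62 and -1.82 for red blood cells, a list no longer called with the block (adjusted p = 0.0670). Under normexp 4790 genes were called.

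The responses of the 2 genotypes ran largely alike across genes, which are not independent replicates. The log2 responses correlated at r = 0.892, 0.842 and 0.844 at 24, 48 and 72 h. At 24 h 8003 genes were called in both genotypes, 8002 of them in the same direction (4379 higher and 3623 lower, where independent lists would share 1331 and 942). At 48 h 4785 of 4788 shared calls had the same direction, and at 72 h 4860 of 4882.

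Genotype comparisons test what differs without miR-155, and first whether the targeted gene does. No probe was matched to the miR-155 host transcript (0 probes), so the arrays give no check of the genotype labels. In saline kidneys Speer4a, Speer4e, Speer5-ps1, Pi4k2b, a phosphatidylinositol kinase, and Scd1, a fatty acid desaturase, were higher in miR-155-/- mice (4 arrays per group). Scd1 was 3.61-fold (1.85 ± 0.20) and Pi4k2b 3.87-fold (1.95 ± 0.22) higher, Speer5-ps1 8.97-fold, Speer4a 9.94-fold (well above background on 2 of 4 wild type arrays), Speer4e at least 4.11-fold and Fam205a2 4.86-fold, the last not borne out by its other probe (-0.06). The osteocalcin genes Bglap2 (-1.27 ± 0.24) and Bglap3 (-0.87), the folate enzyme Mthfd2 (-1.04) and the lamin Lmnb1 (-0.57) were lower. The Nrf2 list was higher, with Gsta2 at 2.03-fold (1.02 ± 0.14) the 1 member called of 16 (median 0.20; adjusted p = 3.87e-07, and 0.0282 with an estimated correlation). S phase genes were lower: 0 of 22 members were called over all genes and 13 adjusted over the list alone (median -0.62; adjusted p = 1.90e-20, and 0.0282 with an estimated correlation). Clock genes were higher, with 0 of 13 called and 3 higher and 1 lower adjusted over the list alone (median 0.42; adjusted p = 6.81e-05, and 0.0282 with an estimated correlation). Of 4 genes reported to differ between C57BL/6J and C57BL/6N, Entpd4, a nucleotide-hydrolysing enzyme, was 1.62-fold higher (median 0.51; adjusted p = 0.00524, and 0.0282 with an estimated correlation), though the median over the list's members was higher on only 1 of 4 miR-155-/- arrays. Of the other lists, neutrophil markers (-0.34), inflammatory genes (-0.26), injury markers (-0.19), p53 targets (-0.11) and adipocyte markers (-1.17) were lower and interferon (0.26), endothelial (0.17) and cholesterol (0.10) genes higher. Their adjusted p lay between 3.99e-07 and 0.0286 and, for the first and last named, adjusted p = 0.0811 and 0.257 with an estimated correlation, 0.607 being the highest of them.

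Of the 26 published miR-155 targets 0 were called in saline kidneys and 1 was higher adjusted over the list alone (median -0.02, mean 0.01). The list was not called at any time, with medians of -0.02, -0.11, -0.10 and 0.02 at 0, 24, 48 and 72 h, camera adjusted p of 0.543, 0.304, 0.452 and 0.346 and fry adjusted p of 0.923, 0.706, 0.492 and 0.764. In saline kidneys 27 genes were called by limma, 21 higher and 6 lower, and the split was 8 and 1 under normexp and 25 and 16 under quantile normalization. All 12 called named genes had 4 of 4 arrays beyond the wild type mean, as the rule requires of the largest rises and falls. Fitted with slide as a block, 22 were higher and 12 lower. Within slides 1, 4 and 6 all 27 kept their sign, on the arrays that they were called on. With the slide block and within these slides the shifts were -0.67, -0.26, -0.64 and -0.39 for S phase genes, 0.13, 0.12, 0.24 and 0.29 for Nrf2 genes and 0.43, 0.42, 0.45 and 0.28 for clock genes. With the block the adipocyte list (-0.99, adjusted p = 0.153) was no longer called and the proximal tubule list was (0.12, adjusted p = 0.00955). Lists called went from 12 to 6 without miR-155-/- 0 h replicate 2. The count of genes was 61 without wild type 0 h replicate 1, 17 without its replicate 2 and 16 without miR-155-/- 0 h replicate 3, and 9 under normexp and 148 with array weights.

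At 24 h after cisplatin 19 genes differed between the genotypes, 15 higher and 4 lower in miR-155-/- kidneys. Among those higher were Tlr6, a receptor for bacterial lipopeptides (10.2-fold, 3.36 ± 0.48), Lgi2 (4.64-fold), Pi4k2b (4.11-fold, 2.04 ± 0.22), Speer5-ps1 (8.08-fold), Speer4e (at least 3.99-fold) and Fam205a2 (5.39-fold; its other probe -0.66). Those lower were Crisp1 (at least 2.23-fold), Bglap2 (-1.72 ± 0.24), the ciliary gene Rsph4a (-1.36) and Bglap3 (-1.15). None of the 10 genes fixed for every comparison passed the test. Nrf2 genes stood higher with 0 of 16 called and 1 adjusted over the list alone (median 0.29), AP-1 genes (median 0.41) and oxidative phosphorylation genes (median 0.12) with 0 called, and Entpd4 was 2.23-fold higher in the C57BL/6J and C57BL/6N list (median 0.57). Adjusted p was 4.81e-05, 0.01, 0.00409 and 0.0288 for these 4 lists, and adjusted p = 0.155, 0.949, 0.949 and 0.155 with an estimated correlation. With slide as a block 12 genes were higher and 3 lower, and within slide 6 all 19 kept their sign. The shifts with the block and within slide 6 were 0.23 and 0.52 for Nrf2 genes, 0.26 (adjusted p = 0.0602) and 0.10 for AP-1 genes and 0.08 and 0.10 for oxidative phosphorylation. Without both divergent arrays 19 were higher and 8 lower, the oxidative phosphorylation shift was 0.08 and the AP-1 list (0.02, adjusted p = 0.883) was not called. Lists called went from 4 to 8 without wild type 24 h replicate 1 and to 7 without miR-155-/- 24 h replicate 1, and under normexp to 7 with 5 genes.

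At 48 h 24 genes differed, 22 higher and 2 lower in miR-155-/- kidneys. Speer4b (18.7-fold; 2 of 4 wild type arrays), Speer5-ps1 (9.84-fold), Speer4a (8.22-fold), Fam205a2 (9.65-fold; its other probe -0.42), Pi4k2b (6.13-fold, 2.62 ± 0.22) and Plac9a (3.44-fold, 1.78 ± 0.23) were higher and the epithelial gene Tmigd1 (-0.61 ± 0.12) lower. Red blood cell markers stood higher, with 0 of 7 called and 7 adjusted over the list alone (median 2.79), beside AP-1 (0.66), S phase (0.37) and injury (0.38) genes, of which 0 were called. Adjusted p was 4.61e-05, 6.22e-04, 2.12e-04 and 0.0474, and adjusted p = 0.633, 0.633, 0.633 and 0.691 with an estimated correlation. Fatty acid oxidation (median -0.29) and distal nephron genes (-0.36) stood lower, with 0 called and, of the latter, 1 adjusted over the list alone. Adjusted p was 1.46e-04 and 0.0296, and adjusted p = 0.633 and 0.649 with an estimated correlation. Adipocyte markers stood lower with them, 0 of 6 called (median -1.67), and interferon (0.24) and cell death genes (0.18) stood higher with 0 called. Adjusted p was 0.0289, 0.0230 and 0.0289, and adjusted p = 0.633 for each with an estimated correlation. Entpd4 was 1.72-fold higher. Under the slide block 68 genes were higher and 3 lower, and within slides 2 and 5 all 24 kept their sign. Fitted with slide as a block, within slide 2 and within slide 5 the shifts were 0.79, 0.93 and 0.33 for AP-1, 0.44, 0.32 and 0.32 for S phase, 0.53, 0.96 and 0.46 for injury, -0.30, -0.38 and -0.34 for fatty acid oxidation, -0.27, -0.29 and 0.44 for distal nephron and 2.83, -0.30 and 3.16 for red blood cell genes. They were 0.39, 1.40 and -0.01 for interferon genes, 0.18, 0.19 and 0.09 for cell death genes and -1.26 (adjusted p = 0.0872), -1.21 and -0.001 for adipocyte markers. Without both divergent arrays 34 were higher and 2 lower, and the shifts were 1.17 for red blood cell, 0.34 for AP-1, 0.18 for S phase, 0.54 for interferon and -1.83 for adipocyte genes, while distal (0.05, adjusted p = 0.928) and cell death genes (0.07, adjusted p = 0.0870) were no longer called. Those called anew were inflammatory (0.42, adjusted p = 1.16e-05), cholesterol (0.22, adjusted p = 1.16e-05) and macrophage genes (0.18, adjusted p = 0.0428) and the C57BL/6J and C57BL/6N list (0.62, adjusted p = 0.00532), and with the block inflammatory (0.29, adjusted p = 0.00772) and proximal genes (-0.23, adjusted p = 0.0238). The count was 14 without wild type 48 h replicate 3, 15 without its replicate 4 and 15 without miR-155-/- 48 h replicate 4. Normexp moved the median of all genes by 0.22 here.

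At 72 h 171 genes differed, 142 higher and 29 lower in miR-155-/- kidneys, among them genes of matrix signalling. Serpinb2, a serpin, was 14.2-fold higher (3.82 ± 0.85), Crct1 11.2-fold and the matrix signalling genes Ccn2 2.94-fold (1.55 ± 0.31) and Tgfb1 1.71-fold (0.78 ± 0.18). Fam205a2 (19.7-fold; its other probe -0.28), Speer4e (14.4-fold; well above background on 1 of 4 wild type arrays) and Speer3 (at least 3.39-fold) were higher too. Egf (-1.35 ± 0.28), Vstm2a (-1.27), the steroid enzyme Hsd3b3 (-1.03), Eaf2, Bglap2 and the methyltransferase Gnmt (each -0.97) were lower. Havcr1 (1.47, adjusted p = 0.369) and Clu (0.64, adjusted p = 0.173) did not pass the test, nor did the other genes fixed for every comparison.

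The intermediate filament gene Vim (2.05-fold, 1.04 ± 0.20) was the 1 of 19 injury markers called, with 13 adjusted over the list alone (median 0.97). The cyclin Ccna2 (2.20-fold, 1.14 ± 0.24) was the 1 of 22 S phase genes called, with 15 adjusted over the list alone (median 0.74). Fibroblast and matrix genes were higher in 3 of 15 cases (9 adjusted over the list alone; median 0.78), and inflammatory genes in 0 of 23 (2 adjusted over the list alone; median 0.52). Adjusted p was 2.04e-14, 2.03e-17, 4.55e-12 and 2.38e-09 for these 4 lists, and adjusted p = 0.0638, 0.0674, 0.0741 and 0.101 with an estimated correlation. Macrophage markers (0 of 15, 3 adjusted over the list alone; median 0.56), neutrophil markers (0 of 9, 3 adjusted over the list alone; median 0.07) and red blood cell markers (0 of 7; median 1.17) moved with them, and interferon genes (0 of 15, 5 adjusted over the list alone; median 0.56). Adjusted p was 2.00e-06, 0.0381, 0.0449 and 7.70e-08, and adjusted p = 0.116, 0.551, 0.605 and 0.114 with an estimated correlation. The organic anion transporter Slc22a6 (-0.72 ± 0.13) was the 1 of 24 proximal genes called lower (3 adjusted over the list alone; median -0.53), and oxidative phosphorylation genes stood lower in 0 of 15 cases (7 adjusted over the list alone; median -0.21). Adjusted p was 4.97e-08 and 1.99e-07, and adjusted p = 0.116 and 0.121 with an estimated correlation. AP-1 (0.47) and cell death (0.19) genes stood higher and fatty acid oxidation genes (-0.19) lower with 0 called (3 of the cell death genes adjusted over the list alone), with adjusted p of 0.00109, 1.42e-04 and 0.0117, and adjusted p = 0.544, 0.116 and 0.552 with an estimated correlation. Entpd4 was 1.68-fold higher, and p53 targets did not differ (median 0.05, adjusted p = 0.687).

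With slide as a block 220 genes were higher and 39 lower, and within slides 3, 7 and 8 the sign was kept by all, all and 170 of the 171. With the slide block and within these slides the shifts were 1.0, 1.02, 1.20 and 1.22 for injury, 0.78, 0.89, 1.18 and 0.99 for S phase, 0.82, 1.67, 0.89 and 0.70 for fibroblast, 0.72, 0.66, 0.66 and 0.68 for inflammatory, 0.75, 0.96, 0.24 and 0.46 for macrophage and -0.40, -0.59, -0.57 and -0.50 for proximal genes, and the red blood cell (0.94, adjusted p = 0.227) and neutrophil (0.06, adjusted p = 0.128) lists were no longer called. All 18 called named genes had 4 of 4 miR-155-/- arrays beyond the wild type mean. The count was 360 without miR-155-/- 72 h replicate 4, 45 and 42 without its replicates 1 and 3, and 47, 64 and 81 without wild type 72 h replicates 1, 2 and 3. It was 63 under normexp, 853 with the compared groups alone and 3400 with array weights.

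**Figure D4:**
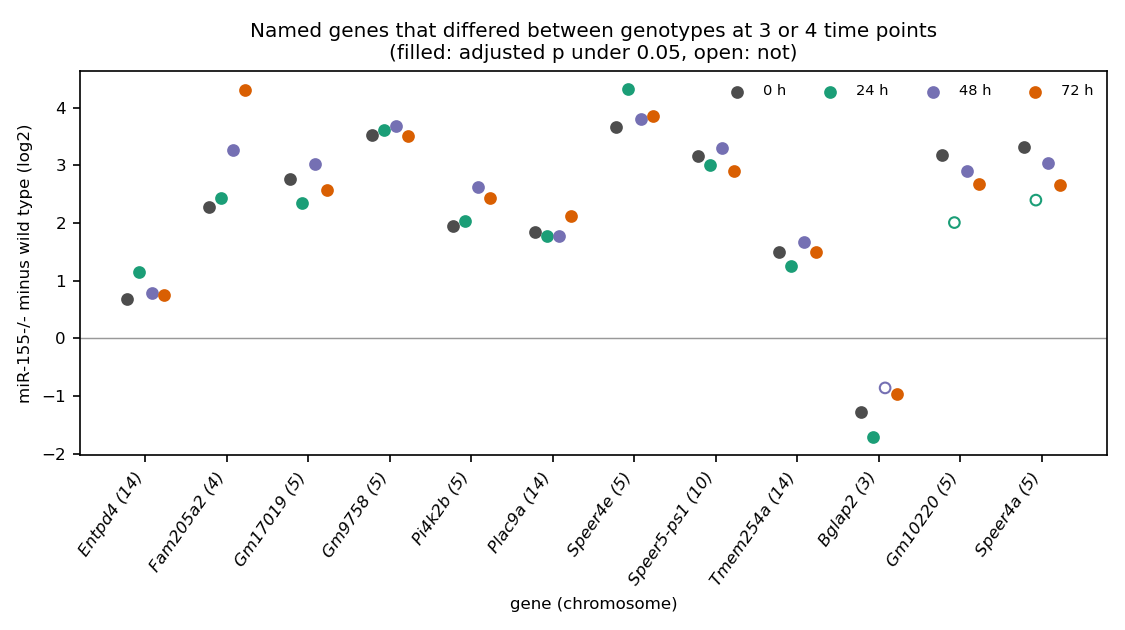
Differences between miR-155-/- and wild type kidneys (log2, 4 arrays per group) at 0, 24, 48 and 72 h for 12 named genes called at 3 or 4 of the times, with filled points for an adjusted p under 0.05. Pi4k2b lies between 1.95 and 2.62 higher at all 4 times, and Bglap2 is the one gene that lies lower.

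The genotype genes recurred over time. Of 186 genes called at 1 time or more, 11 were called at all 4, among them Entpd4, Pi4k2b, Plac9a and Tmem254a. A further 4 were called at 3 times, 14 at 2 and 157 at 1. These genes were singled out after their values were seen.

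The interaction compares responses by genotype, so 0 h differences enter it. At 24 h limma called 0 genes (2 under quantile normalization). S phase genes responded more in miR-155-/- kidneys, with 0 of 22 called (median 0.54; array scores differed by -0.63 in saline kidneys and -0.03 at 24 h), as did injury markers (median 0.47) and neutrophil markers (0 of 9 called, 3 adjusted over the list alone; median 0.46), and clock genes less (0 of 13 called, 4 adjusted over the list alone; median -0.35). Adjusted p was 4.30e-09, 0.00233, 0.00233 and 0.00233, and adjusted p = 0.612, 0.633, 0.633 and 0.165 with an estimated correlation. Markers of red blood cells (median 1.19), endothelium (-0.33) and adipocytes (1.67) moved with them, with adjusted p of 0.0281, 0.0281 and 0.0291, and adjusted p = 0.633 for each with an estimated correlation. With slide as a block the shifts were 0.51 for S phase, 0.39 for injury and 0.80 for neutrophil and 2.16 for red blood cell genes and -0.35 for clock genes, and the endothelial and adipocyte lists were no longer called (adjusted p = 0.314 and 0.339). Within slide 6, which holds 1 array of each of the 4 groups, the shifts were 0.25 for S phase, 0.54 for injury, 0.24 for neutrophil, 2.73 for red blood cell, -0.26 for endothelial, 4.32 for adipocyte and -0.37 for clock genes. Without both divergent arrays the shifts were 0.44 for S phase, 0.23 for injury and -0.02 for neutrophil genes and -0.27 for clock genes, and the red blood cell (0.55), endothelial (-0.24) and adipocyte (1.51) lists were no longer called (adjusted p = 0.129, 0.129 and 0.0981). Inflammatory (0.16), cell death (0.11), unfolded protein response (0.33) and oxidative phosphorylation genes (0.11) also responded more, with 0 called and adjusted p of 0.0216, 0.0281, 0.0118 and 0.0216 (adjusted p = 0.633 for each with an estimated correlation). With the block and within slide 6 these were 0.28 and 0.09, 0.14 (adjusted p = 0.0953) and 0.13, 0.41 and -0.02, and 0.04 (adjusted p = 0.0953) and 0.02, and without both divergent arrays 0.28, 0.09, 0.17 (adjusted p = 0.189) and 0.05 (adjusted p = 0.129). The number of lists called went from 11 to 6 without both divergent arrays, to 7 without wild type 0 h replicate 2, miR-155-/- 0 h replicate 1 or miR-155-/- 24 h replicate 4, and to 6 without wild type 24 h replicate 3, and 1 gene was called without miR-155-/- 24 h replicate 1.

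At 48 h limma again called 0 genes (4 under quantile normalization, 6 with slide as a block, 24 with array weights). S phase genes responded more in miR-155-/- kidneys (0 of 22 called, 17 adjusted over the list alone; median 0.91), as did inflammatory genes (0 of 23; median 0.74), neutrophil markers (0 of 9, 3 adjusted over the list alone; median 0.75) and red blood cell markers (0 of 7, 1 adjusted over the list alone; median 3.01). Adjusted p was 4.81e-16, 8.48e-05, 9.29e-05 and 7.76e-05, and adjusted p = 0.266, 0.391, 0.391 and 0.391 with an estimated correlation. Under the slide block the shifts were 1.09, 1.01, 1.01 and 3.63 in the same order, and without both divergent arrays 0.71, 0.88, 0.55 and 1.37. No slide held all 4 groups at 48 or 72 h. Distal nephron (-0.43), fatty acid oxidation (-0.29) and clock genes (-0.34) responded less and AP-1 (0.65), injury (0.50), cell death (0.20) and p53 target genes (0.20) more, with 0 called (1 of the clock genes adjusted over the list alone) and adjusted p between 0.00469 and 0.0424 (adjusted p = 0.391 to 0.75 with an estimated correlation). With the block the shifts were -0.41, -0.31, -0.40, 0.72, 0.76, 0.21 and 0.32, and without both divergent arrays p53 targets stood at 0.09, and distal (0.01, adjusted p = 0.496) and AP-1 genes (0.24, adjusted p = 0.338) were no longer called. Those called anew were Nrf2 (-0.19, adjusted p = 0.00810), macrophage (0.38, adjusted p = 0.00552) and interferon genes (0.27, adjusted p = 0.0115), and with the block proximal (-0.36, adjusted p = 0.00121), oxidative phosphorylation (-0.11, adjusted p = 0.0275) and fibroblast genes (0.56, adjusted p = 0.0417). The count was 8 without wild type 0 h replicate 1, 1 without wild type 48 h replicate 1 and 2 without miR-155-/- 48 h replicate 2. Lists called went from 11 to 7 without miR-155-/- 0 h replicate 2 and to 5 without wild type 48 h replicate 3. Normexp moved the median of all genes by 0.18.

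At 72 h genes of DNA replication and mitosis responded more in miR-155-/- kidneys, and 50 genes were called, 41 higher and 9 lower (3 and 2 under normexp). Rad51ap1 (2.07 ± 0.31), Pole (1.21 ± 0.19) and Dtl (3.08 ± 0.52) of replication and repair were higher. So were Cenph (2.34 ± 0.36), Ccna2 (2.11 ± 0.34), Lmnb1 (1.05 ± 0.16), S100a4 (1.59 ± 0.25) and Loxl4 (2.69 ± 0.45). Gsta2 (-1.26 ± 0.20) and Gm10639 (-1.17 ± 0.20) were lower. Adjusted p was 0.00293 to 0.00637. At 0 h Gsta2, Lmnb1 and the S phase score (-0.63) differed the other way. Of 22 S phase genes 4 responded more, Ccna2, Ccnb1, Top2a and Mki67, and 18 adjusted over the list alone (median 1.37; adjusted p = 5.79e-30, and 0.0215 with an estimated correlation). Of 19 injury markers Vim did (1.31 ± 0.28), and 9 adjusted over the list alone (median 1.32; adjusted p = 3.74e-13, and 0.0467 with an estimated correlation). Havcr1 (1.69 ± 0.90, 95% interval -0.16 to 3.54, adjusted p = 0.714) and Lcn2 (1.26 ± 0.96, adjusted p = 0.864) did not pass the test.

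Of 9 neutrophil markers S100a9 (4.76 ± 0.91) and S100a8 (4.94 ± 0.97) responded more (3 adjusted over the list alone; median 0.35), as did 0 of 23 inflammatory genes (7 adjusted over the list alone; median 1.14), 0 of 15 fibroblast genes (6 adjusted over the list alone; median 0.92) and 0 of 15 macrophage markers (1 adjusted over the list alone; median 0.81). Adjusted p was 1.24e-05, 6.18e-13, 3.10e-10 and 9.59e-06, and adjusted p = 0.140, 0.0551, 0.103 and 0.164 with an estimated correlation. Red blood cell markers moved with them (median 1.36, adjusted p = 0.0415, and adjusted p = 0.548 with an estimated correlation; 1.65 and adjusted p = 0.0667 with slide as a block). Proximal tubule (-0.52), oxidative phosphorylation (-0.21) and clock genes (-0.52) responded less and cell death (0.24), interferon (0.28) and p53 target genes (0.16) more, with 0 called (1, 0, 3, 3, 0 and 0 adjusted over the list alone) and adjusted p of 1.05e-06, 1.24e-05, 0.00584, 8.54e-05, 0.0127 and 0.0390, and adjusted p = 0.174, 0.224, 0.103, 0.119, 0.508 and 0.517 with an estimated correlation. With the block these shifts were -0.57, -0.24, -0.65, 0.20, 0.40 and 0.21, the last no longer called (adjusted p = 0.0667), and Nrf2 genes (-0.11, adjusted p = 0.0365) were called anew. The p53 scores differed by -0.14 at 0 h and -0.003 at 72 h. The block called 153 genes. Shifts were 1.43 for S phase, 1.39 for injury, 1.24 for inflammatory, 1.15 for fibroblast, 1.05 for macrophage and 0.50 for neutrophil genes. Leaving out 1 array gave 101 calls without wild type 0 h replicate 1 and 13 without its replicate 2, 16 and 30 without miR-155-/- 0 h replicates 1 and 3, and 12, 23 and 17 without wild type 72 h replicates 1, 2 and 3. It gave 13, 20, 12 and 160 without miR-155-/- 72 h replicates 1, 2, 3 and 4. The count was 5 under normexp, 32 with no filter on dim probes, 96 higher and 11 lower under quantile normalization, 672 with the compared groups alone and 1147 with array weights.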

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

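The tests of recurring genes, of single arrays and of the S phase response, and the counts of other splits, were chosen after the results were seen. The test of genes near Mir155 was fixed before.

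Pattern 1 is the set of genes that differed between the genotypes at 2 or more times, found in a signal that runs through all 4 times. Of 20 such genes with a position 10 lay on chromosome 5, which holds 6.10% of the tested genes (odds ratio 15.5, adjusted p = 1.58e-06 over the chromosomes, 2-sided Fisher exact test), and they include Pi4k2b, Tlr1, Tlr6, Lgi2 and Speer genes that neighbour each other. Inherited DNA of another origin on a chromosome other than that of Mir155 stays open. The test counted neighbours and near-identical Speer copies as independent and cannot decide. Flanking DNA around the targeted allele stays open: 0 of 116 genes within 20 Mb of Mir155 were called at each time (odds ratio 0), but the intervals reach up to 4.33 at best and 43.0 at worst. Loss of miR-155 itself was not separated from either, since the animals of 1 line share all of these.

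Pattern 2 is miR-155-/- replicate 3 at 48 h, whose mean correlation with its group was 0.960 where the others gave 0.982 to 0.983. Array signal quality is argued against, since 0 of its 6 measures lay outside the range of the other 31 arrays. Blood in the tissue stays open: dropping the few red blood cell genes (0.960, the other 3 at least 0.993) could hardly move a correlation over all genes. A kidney of the 24 h group could lie under this label: on an axis from wild type 24 h (0) to 48 h (1) the array stood at 0.046, and its nearest array was miR-155-/- replicate 3 at 24 h (r = 0.983), but its mean correlation with the other 3 arrays of that group (0.964) was below that of this replicate with them (0.968) and the lowest among them (0.988), so it stays open. No array labelled 24 h stood above 0.173 on that axis, as a partner in an exchange would. RNA quality and a different course of injury were not tested.

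Pattern 3 is the larger S phase and mitosis response of miR-155-/- kidneys at 72 h (median difference 1.37). Slide is argued against, since the median with slide as a block was 1.43 (adjusted p = 2.36e-21). The saline difference is part of it. Array scores differed by -0.63 at 0 h and 0.74 at 72 h and changed by 0.67 in miR-155-/- and -0.71 in wild type. Exact permutation p was 0.0286 (the smallest 4 against 4 arrays allow), 0.0571, 0.0857 and 0.0286. More dividing immune cells stay open: marker medians ran from -0.14 for lymphocytes to 0.81 for macrophages. A direct effect of miR-155 loss on cell division was not tested.

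The interaction called 50 genes at 72 h, and 11, 11 and 13 gene lists at 24, 48 and 72 h, numbers of lists that other splits reached too. The genes with the smallest adjusted p were Rad51ap1 (2.07), Lmnb1 (1.05), Cenph (2.34), S100a4 (1.59), Pole (1.21), Ccna2 (2.11), Gsta2 (-1.26), Loxl4 (2.69), Dtl (3.08) and Gm10639 (-1.17). Tubular injury markers (1.32) and S phase genes (1.37) at 72 h were the lists that held with an estimated correlation.

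Single arrays far from the other 3 of their group were sought over the 10 fixed genes, 27 list scores and 2 array measures. Of 311 groups 20 met the criterion, where chance gives 15.6. On the log2 scale Havcr1 stood at 0.58 in wild type 24 h replicate 3 (others from 1.60), at -0.82 in miR-155-/- 24 h replicate 3 (others from 1.09) and at 0.12 in miR-155-/- 48 h replicate 3 (others from 2.63). That last array also had Cdkn1a at 4.54 (others to 3.07) and scores of 2.02 for AP-1 genes (others to 0.47), -0.83 for cisplatin transport (others from -0.01) and -0.81 for the proximal tubule (others from -0.15). In miR-155-/- 72 h replicate 4, Cdkn1a stood at 2.66 (others from 3.1), Atf3 at 0.48 (others from 1.0) and the S phase score at -0.28 (others from 0.56). Mdm2 stood at 5.14 in wild type 72 h replicate 3 (others to 4.71) and Hmox1 at 1.23 in wild type 0 h replicate 3 (others to 0.95). In miR-155-/- 0 h replicate 3 the AP-1 score was -0.97 (others to -1.47) and the macrophage score 0.33 (others from 0.44). The distal nephron score was 1.09 in wild type 0 h replicate 1 (others to 0.63), and the macrophage score 1.21 in its replicate 2 (others to 0.54). In wild type 24 h replicate 1 the neutrophil score was 0.52 (others to -0.19) and the podocyte score -0.66 (others from 0.01), and in replicate 4 the adipocyte score was 2.62 (others to -0.78).

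Splits of the same arrays into other groups of 4, 35 for each pair of groups and 100 drawn for an interaction, were set against the real counts of genes. Chance was excluded for 9182, 5655, 6018, 11667, 10398 and 8367 in the cisplatin comparisons (highest other 3, 569, 0, 2014, 1259 and 25), for 27, 24 and 171 between the genotypes at 0, 48 and 72 h (highest other 18, 8 and 1) and for 50 in the interaction at 72 h (highest other 5), each with 1 split as large, the real one. For the 19 genes between the genotypes at 24 h 2 splits were as large, the real one among them, so chance stays open there too. The counts of 0 in the interactions at 24 and 48 h cannot be tested so. The splits take no account of slide. The split of 24 h arrays with 45 calls joined replicates 1 and 2 of miR-155-/- with 1 and 3 of wild type, and its cause was not tested. For the numbers of lists called chance was not excluded in any comparison. In the cisplatin comparisons 14, 13, 5, 5, 7 and 13 of 35 splits reached the real 12, 14, 17, 13, 13 and 14 (highest other 17, 19, 19, 15, 15 and 17). Between the genotypes 4, 33, 17 and 6 reached 12, 4, 9 and 14 (highest other 13, 13, 15 and 15), and in the interactions 19, 28 and 13 of 100 reached 11, 11 and 13 (highest other 14, 17 and 20).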

How the results depend on the processing

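Scan day as a block and the fit without both divergent arrays were chosen after the data were seen. Of the counts set against alternatives, 305 stayed within 1.5 times and 66 did not, and for those the cause was not tested unless said. Of 767 values of named genes, 647 kept direction and call under normexp, 762 under quantile normalization, 746 with slide as a block, 751 with scan day and 767 in the deposited value table. Those reversed were Cd3d (0.16), Cd8a (0.41) and Cd3g (0.30) under normexp in miR-155-/- at 48 h, with adjusted p of 0.85, 0.66 and 0.73.

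Normexp called 5247, 2978, 3044, 7144, 5187 and 4790 genes in the cisplatin comparisons, 9, 5 and 63 between the genotypes at 0, 24 and 72 h, with 7 lists at 24 h, and 5 in the interaction at 72 h. Quantile normalization called 41 genes between saline groups and 2, 4 and 1.1e+02 (96 higher and 11 lower) in the interactions. Without the dim filter 14 lists were called between the genotypes at 48 h and 32 genes in the interaction at 72 h. Slide as a block gave 71 and 259 genes between the genotypes at 48 and 72 h, 7 lists in the interaction at 24 h, and 6 and 153 genes in those at 48 and 72 h. Array weights gave 11018 and 12564 genes in wild type at 48 and 72 h, 148, 137 and 3400 between the genotypes at 0, 48 and 72 h, 1 list in the interaction at 24 h, and 24 and 1147 genes at 48 and 72 h. With only the groups compared, which leaves fewer arrays, 9734 (wild type 72 h) and 5808 (miR-155-/- 48 h) were called, 17, 12, 1 and 853 between the genotypes and 672 in the interaction at 72 h. The 2-fold threshold, stricter by construction, left 3228, 1971, 2321, 4443, 3781 and 3316, and 113 between the genotypes at 72 h. Camera with an estimated correlation called 1, 3, 3, 1, 1 and 4 lists, then 4, 0, 0 and 0 between the genotypes and 0, 0 and 2 in the interactions. Fry, which asks another question, called 0, 1, 1 and 8, and 0, 0 and 4. Without both divergent arrays 6 lists were called in the interaction at 24 h.

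Same-numbered replicates did not deviate together (median r 0.004, from -0.55 to 0.59, 33 of 112 pairs above 0.1), so that the number pairs no samples. Arrays of the same slide in different groups did (median r 0.244, 34 of 48 pairs above 0.1), which the main fit leaves out of account and the slide block takes in. With the replicate block the interaction at 72 h called 30 genes, and all other counts stayed within 1.5 times.

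Leaving out each array gave 7475 to 8973, 4160 to 5684 and 4669 to 5553 genes in wild type and 10117 to 11992, 7827 to 10952 and 7174 to 8242 in miR-155-/-, with 11 to 13, 14 to 16, 15 to 18, 11 to 13, 12 to 15 and 14 to 16 lists. Between the genotypes it gave 16 to 61, 13 to 21, 14 to 36 and 42 to 360 genes and 6 to 14, 3 to 8, 6 to 12 and 12 to 15 lists. In the interactions it gave 0 to 1, 0 to 8 and 12 to 160 genes and 6 to 11, 5 to 13 and 12 to 16 lists. The arrays behind moves beyond 1.5 times are named with the comparisons. The seed site test and its 8mer form were not run.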
